A study of Arabidopsis thaliana with 2 samples.

How the data were processed

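Two-colour Agilent arrays were used to compare RNA of auxin-treated and control seedlings, with 2 arrays in the series. Per the labels, 500 ng of RNA was labelled for each sample, Cy5 marks seedlings after 6 h of auxin and Cy3 marks control seedlings at 0 h, on both arrays. The labelling text of the labels names a different treatment (cis-CA) for Cy5, while titles, sources and treatment text name auxin, which was followed here. The arrays lie on the same slide and were scanned together, per the file headers, so no slide or scan batch could be tested.

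The deposited files hold spot intensities: mean foreground and median local background intensity of each channel, per the file headers, made with Agilent Feature Extraction. The file headers name version 10.5.1.1 and the submitters' processing notes 8.5.1.1. The authors also deposited log10 ratios of Cy5 over Cy3 after the software's own background and dye correction, and a value table that repeats these log10 ratios in rounded form. Against the scanner column, with a tolerance of 0.006, 14 values of replicate 1 and 40 of replicate 2 in the value table equalled the next spot's value, and 116 and 126 cells were empty. Its scale, centring and direction are those of the scanner column, and the median of each array's column was 0. Median Cy3 intensity was 373 and 353 on replicates 1 and 2, and median Cy5 intensity 535 and 498, over local backgrounds of 40 and 42 in Cy3 and 57 and 56 in Cy5. Well above background were 69.5% and 66.9% of 43803 spots in Cy3, and 73.0% and 71.6% in Cy5. No spot was saturated, and 15 and 8 spots carried outlier marks. Spike-in ratios had a slope of 0.908 and 0.911 against the expected log ratio, per the file headers, for the scanner's own ratios. In the log2 ratios used here, all 10 spike-ins lay nearer to 0, most of all one that went from 2.18 and 2.20 on the 2 arrays to 0.43 and 0.53, and another from -0.92 and -0.73 to -0.18 and -0.14.

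Background was corrected with normexp (offset 50), log2 ratios were normalized by loess within each array with control spots at weight 0, outlier spots were left out, and spots of a probe were averaged (R 4.3.3, limma 3.58.1). A probe was kept when it was well above background in at least 1 channel on both arrays. Of 43603 probes, 37540 name 1 locus, 873 several and 5190 none, and those without exactly 1 locus were left out of the gene tests. Each of the 20928 genes tested was measured by its brightest probe. Of 57 changed genes with several probes, 1 had probes of opposite sign (ORP4C, with -0.03 and 2.19). Of 28479 loci, 28074 were found in the RefSeq gene table of assembly TAIR10.1, which was used for names alone. Probe positions come from the array design.

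The mean log2 ratio of the 2 arrays was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There was 1 residual degree of freedom, with 2.88 prior degrees of freedom added from all genes. The p-values of single genes measure the spread between these arrays, which the labels call biological replicates. Before the data were examined, 41 gene lists with 604 loci (572 tested) were fixed from general knowledge. They were tested with camera at a preset correlation of 0.01, with a correlation estimated from the arrays, and with fry, each adjusted over the lists. Camera at the preset correlation sets a list's genes against all others, so its p-values do not measure a list's spread between the arrays. The genes named were fixed by rule too: the 12 highest and 12 lowest genes past the threshold by the smaller of the 2 arrays' ratios, up to 4 changed members of each list or else the 2 most extreme, and 2 genes of opposite sign. Other members and genes are named after their values were seen. Where a gene was not well above background in a channel on both arrays, the fold is a bound, "at least", against the lowest normalized signal among probes well above background, or the gene's own if higher, after loess and quantile normalization of mean intensities. The bound concerns the dim channel alone: it uses the mean of the 2 arrays and makes no allowance for their spread.

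The scripts were tested on simulated data for the 20928 genes, with 200 changed genes in each of 5 runs. The share recovered was 0.4% at a log2 change of 1, 32.8% at 2, 85.6% at 3 and 96.0% at 4, and 6.93% of all calls were false. These shares hold for 200 changed genes, while 321 genes were called in the data, and other numbers of changed genes were not simulated. With a list of 12 genes shifted by 1, camera at the preset correlation found it in 5 of 5 runs. With the estimated correlation it was found in 0 of 5, so that with 2 arrays this setting has little power for such a shift. Larger list shifts and fry were not simulated. Simulated genes were drawn independently. The runs therefore do not show how often camera at the preset correlation is wrong for lists whose genes move together. Alternatives covered background correction, the authors' processed ratios, normalization, filters, probe summary, test settings, thresholds and each array alone.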

Results

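The series asked which transcripts differ between Arabidopsis thaliana seedlings kept in auxin and control seedlings. Whole Col-0 seedlings, 14 days old, were moved from agar with 1% sucrose to 20 ml of water for 1 h and then to water with auxin at 20 µM, with dimethyl sulfoxide at 0.0125%. The labels do not name the auxin compound. Seedlings taken at 0 h were the control and those taken at 6 h the treated group. Each of 2 arrays carried treated RNA labelled with Cy5 and control RNA labelled with Cy3, and the labels call the arrays biological replicates. Replicate 1 had 30431 spots well above background in Cy3 and 31955 in Cy5, of 43803, and replicate 2 had 29302 and 31369. The number of arrays, 2, limits the precision of every value below.

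After auxin, the lists of early auxin response genes were higher, and those of root-hair and glucosinolate genes lower, with camera at a preset correlation. These list calls were lost with an estimated correlation (adjusted p = 0.722 or more) and with fry (adjusted p = 0.199 or more). GH3.3 (AT2G23170), which conjugates auxin to amino acids, rose 125-fold, with log2 ratios of 6.81 and 7.12 on the 2 arrays. The Aux/IAA repressor genes IAA5 (AT1G15580), IAA29 (AT4G32280) and IAA1 (AT4G14560) rose 57.1-fold, 39.7-fold and 30.1-fold. NRT1.5 (AT1G32450), a nitrate transporter gene of the root, fell by 4.08 on the log2 scale, and BCAT4 (AT3G19710), an enzyme of methionine-derived glucosinolate synthesis, fell by 3.74. Across 20928 genes, 152 rose and 169 fell at an adjusted p under 0.05 (limma), and the smallest change among them was 1.53 on the log2 scale. At an unadjusted p under 0.05 the count was 3669 genes, and the smallest adjusted p of any gene was 0.0267, shared by 62 genes.

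The 12 genes that rose most on both arrays also included GH3.1 (AT2G14960, mean log2 ratio 4.42), the germin-like gene AT5G38910 (4.45) and LBD17 (AT2G42440, 4.22), a gene of the lateral organ boundaries family. GATA23 (AT5G26930), known for its part in lateral root founder cells, had a mean of 4.09, with IAA19 (AT3G15540) at 4.19 and MAKR4 (AT2G39370) at 4.15. ACS4 (AT2G22810), which encodes an ethylene precursor synthase, had 3.91. The glutathione transferase gene GSTU12 (AT1G69920) had 6.00 on replicate 1 and 4.08 on replicate 2. The moderated standard errors of these 12 means lay between 0.16 and 0.51, with n = 2 arrays and GSTU12 the least precise. Adjusted p was 0.0478 for GSTU12, 0.0303 for MAKR4 and 0.0267 for the other 10 genes. IAA5, AT5G38910, LBD17 and ACS4 were well above background in the control on 1 of the 2 arrays. The probe of GH3.3 lies on chromosome 2 at 9871102 to 9871161 and that of IAA5 on chromosome 1 at 5365771 to 5365918, in the array design's ath1 build.

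The 12 genes that fell furthest on both arrays included several that are known from root hairs. Among them were COBL9 (AT5G49270, mean log2 ratio -3.71), EXPA7 (AT1G12560, -3.38), MRH6 (AT2G03720, -3.64), RHS18 (AT5G22410, -3.67) and RHS8 (AT1G63450, -3.49). The others were NRT1.5, BCAT4, the cellulase gene GH9C1 (AT1G48930, -3.68), AT5G57625 (-4.00), the peroxidase genes AT1G30870 (-3.47) and AT3G49960 (-3.41), and MAM3 (AT5G23020, -3.35). Adjusted p was 0.0267 for all 12, and the arrays differed by 0.36 or less for each of them. RHS8 was well above background in the treated channel on 1 of the 2 arrays. The NRT1.5 probe lies on chromosome 1 at 11715326 to 11715385 and that of BCAT4 on chromosome 3 at 6847283 to 6847440.

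**Figure D1:**
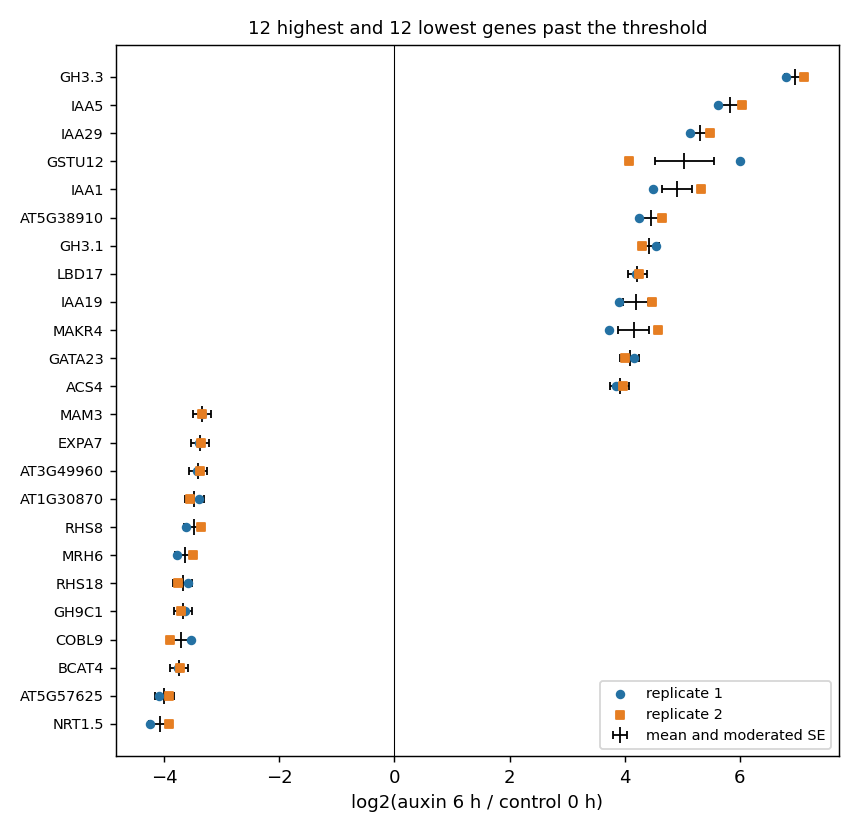
The horizontal axis gives the log2 ratio of auxin at 6 h over control at 0 h for the 12 highest and 12 lowest genes past the threshold, with circles for replicate 1, squares for replicate 2, and bars for the mean and its moderated standard error. GH3.3 lies highest at a mean of 6.97 and NRT1.5 lowest at -4.08, and GSTU12 has the widest gap between the arrays.

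Genes that respond to auxin early rose as groups. Of 28 Aux/IAA genes tested, 10 rose, 0 fell and 18 did not pass, or 20 rose and 3 fell when adjusted over the list alone. The list's median log2 ratio was 1.51 on replicate 1 and 2.06 on replicate 2 (camera adjusted p = 8.76e-13, and adjusted p = 0.754 with an estimated correlation). Of 11 genes for auxin conjugation and inactivation, 6 rose and 0 fell, by either adjustment, with medians of 3.33 and 3.05 (adjusted p = 8.61e-06, and adjusted p = 0.722 with an estimated correlation). The other 5 lay between -0.30 and 0.45, and the median of the list was 0.45 with no filter. Those that rose included GH3.2 (18.3-fold) and GH3.6 (10.9-fold). Of 26 SAUR genes, which are short auxin-induced transcripts linked to cell expansion, 4 rose and 0 fell, or 20 and 0 when adjusted over the list alone. Their medians were 1.83 on replicate 1 and 2.78 on replicate 2 (camera adjusted p = 5.06e-13, and adjusted p = 0.722 with an estimated correlation). SAUR10, well above background in the control on 1 of the 2 arrays, rose 13.4-fold, SAUR15 9.63-fold and SAUR1 3.91-fold. SAUR68, one of the near-identical genes set aside below and not well above background in the control on either array, rose at least 6.41-fold. Without the 14 near-identical SAUR genes whose probes can share transcripts, the remaining 12 had a median of 0.89, in place of 2.37 for the whole list (adjusted p = 1.47e-04, and adjusted p = 0.722 with an estimated correlation). Of the 12, 3 rose and 0 fell over all genes. The 14 left out were all among the 20 that rose when adjusted over the list alone.

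Auxin transport genes were shifted upward as a list, with medians of 0.38 and 0.33, while 0 of 18 passed on their own, or 3 rose and 1 fell when adjusted over the list alone (adjusted p = 0.00901, and adjusted p = 0.754 with an estimated correlation). PIN3 had a mean of 1.96 and PILS5 of 1.49. Auxin biosynthesis genes were shifted downward, with medians of -0.35 and -0.42 and 0 of 11 passing, or 1 fell when adjusted over the list alone (adjusted p = 0.0255, and adjusted p = 0.754 with an estimated correlation), a call also lost at an adjusted p under 0.01. TAA1, which makes the indolepyruvate precursor of auxin, had -1.07 on both arrays, and YUC6 had a mean of -0.75. Auxin receptor and response factor genes, 17 in number, had a median of 0.09 with 0 passing by either adjustment (adjusted p = 0.531), and their highest members were ARF10 at 0.85 and ARF4 at 0.80.

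Genes of lateral root initiation rose. Of 23 tested, 9 rose and 1 fell, or 13 and 3 when adjusted over the list alone, and the medians were 1.29 on both arrays (adjusted p = 4.13e-07, and adjusted p = 0.722 with an estimated correlation). Besides LBD17 and GATA23, PUCHI rose 12.5-fold and LBD33, not well above background in the control, rose at least 13.6-fold. In the list for ethylene synthesis, 2 of 12 genes rose and 1 fell, or 5 and 1 when adjusted over the list alone, with medians of 1.61 on replicate 1 and 0.52 on replicate 2 (adjusted p = 0.0132, and adjusted p = 0.754 with an estimated correlation). The call was also lost with median centring, with both channels required and at an adjusted p under 0.01. ACS4 rose 15.1-fold and ACS11 7.61-fold, while ACO5 fell by 1.87 on the log2 scale. Ethylene response genes had medians of 0.73 and 0.80, and 11 of 12 lay above 0 on both arrays. None passed over all genes and 9 rose when adjusted over the list alone (adjusted p = 8.61e-06, and adjusted p = 0.722 with an estimated correlation). HCHIB had a mean of 1.55 and ERF1 of 1.46.

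Type-A ARR genes, the cytokinin-induced response regulators, were lower, with medians of -0.72 and -1.31. Of 9 tested, 0 rose and 1 fell, or 6 fell when adjusted over the list alone (adjusted p = 5.07e-05, and adjusted p = 0.722 with an estimated correlation). ARR6, not well above background after auxin, fell to a level at least 7.87-fold lower, and ARR7 had -1.32. Gibberellin metabolism genes had medians of 1.15 and 0.90, with 0 of 9 passing over all genes and 4 rising when adjusted over the list alone (adjusted p = 0.00157, and adjusted p = 0.754 with an estimated correlation). The call was lost with median centring, and the median was 0.49 with no filter. The highest, GA2OX2 at 1.69 and GA2OX8 at 1.60, encode enzymes that inactivate gibberellins. The cytokinin metabolism list did not pass (adjusted p = 0.699), with CKX6 at 2.40 and CKX1 at 1.80, nor did brassinosteroid metabolism (adjusted p = 0.591), with BAS1 at 1.61 and BR6OX1 at -0.62, the latter well above background after auxin on 1 array. Abscisic acid genes did not pass (adjusted p = 0.232), with RD22 at -1.31, and NCED5 was not well above background in the control and did not pass (adjusted p = 0.0693). Jasmonate genes did not pass (adjusted p = 0.285), with CYP94B3 at 1.68 and CORI3 at -1.51. In these 4 lists no member passed over all genes, and adjusted over the list alone 2 rose and 1 fell for cytokinin, 1 rose for brassinosteroids, 2 rose and 1 fell for abscisic acid and 0 passed for jasmonate.

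Root-hair markers fell. Of 6 tested, 0 rose and 5 fell, or 6 fell when adjusted over the list alone, with medians of -3.21 and -2.86 (adjusted p = 3.21e-09, and adjusted p = 0.722 with an estimated correlation). RSL4, a regulator of root-hair growth, fell by 2.94 on the log2 scale, and EXPA18, not well above background after auxin, was at least 8.93-fold lower. Markers of the endodermis and root cap had medians of -1.27 and -0.69, with 0 of 9 passing over all genes and 5 falling when adjusted over the list alone (adjusted p = 5.49e-04, and adjusted p = 0.754 with an estimated correlation). CASP1 had -3.04 on replicate 1 and -1.16 on replicate 2, and ESB1 had -2.11 and -0.75. The markers of stomata (adjusted p = 0.461), shoot meristem (0.232) and vascular tissue (0.283) did not pass as lists, and 0 members passed by either adjustment. KAT1 had -0.58 and MUTE -0.21, KNAT1 had 0.92 and CUC1, well above background in the control on 1 array, 0.22, and IRX5 had -0.60 and HB8 0.45.

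Glucosinolate genes, which make the sulfur-rich defence compounds of the cabbage family, fell. Of 18 tested, 0 rose and 6 fell, or 13 fell when adjusted over the list alone, and the medians were -1.71 and -1.47 (adjusted p = 3.98e-12, and adjusted p = 0.722 with an estimated correlation). CYP79F1 fell to a level 8.01-fold lower and BAT5 to a level 7.33-fold lower, beside BCAT4 and MAM3. Sulfate starvation genes had medians of -0.08 on replicate 1 and -1.75 on replicate 2, with 0 of 12 passing, or 2 falling when adjusted over the list alone (adjusted p = 8.09e-04, and adjusted p = 0.754 with an estimated correlation). SULTR1;1, well above background after auxin on 1 of the 2 arrays, had a mean of -2.72, and APR3 had -1.46. Nitrate response genes had medians of -0.37 and -0.50, with 0 of 13 passing, or 3 falling when adjusted over the list alone (adjusted p = 0.00915, and adjusted p = 0.754 with an estimated correlation), and NRT2.1 had -2.32 and UPM1 -0.95. Of these 13 genes, 7 differed in sign between the arrays and 5 lay below 0 on both. With median centring the nitrate list lost its call (adjusted p = 0.113), and its median changed sign to 0.22, nearer to the median of all genes, 0.31 in that setting, than before. Of 8 iron deficiency genes 1 fell, or 2 when adjusted over the list alone, and the list did not pass (adjusted p = 0.0925). The regulator FIT fell to a level 4.14-fold lower, and NAS4, well above background after auxin on 1 array, had -0.88. Flavonoid genes had medians of -0.48 on both arrays, with 0 of 11 passing, or 1 rising and 4 falling when adjusted over the list alone (adjusted p = 0.0244, and adjusted p = 0.754 with an estimated correlation). That call was also lost with the authors' log ratios, the value table and an adjusted p under 0.01. FLS1 had a mean of -1.61 and CHS, the chalcone synthase gene, of -1.17.

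Cell cycle lists were shifted downward by small amounts. Mitotic genes had medians of -0.53 and -0.24, and 14 of 17 lay below 0 on both arrays (adjusted p = 6.59e-05, and adjusted p = 0.754 with an estimated correlation). S-phase genes had medians of -0.43 and -0.27, with 12 of 17 below 0 on both arrays (adjusted p = 7.66e-04, and adjusted p = 0.722 with an estimated correlation). No member of either list passed by either adjustment, and the most extreme were CDKB1;2 at -0.79 and CYCB1;4 at -0.65, and CDT1A at -0.78 and PCNA1 at -0.64. With median centring, which put the median of all genes at 0.31, the mitotic median was -0.14 and the S-phase median -0.02, and their distance below the median of all genes did not shrink. Morning clock genes were higher, with medians of 0.58 and 0.75 and 11 of 13 above 0 on both arrays. CCA1 rose 4.13-fold and was the 1 member to pass, or 10 rose when adjusted over the list alone (adjusted p = 3.71e-05, and adjusted p = 0.722 with an estimated correlation), and RVE1 had 1.67. Evening clock genes had a median of 0.11, and 0 of 10 passed by either adjustment (adjusted p = 0.699), with BOA at 0.85 and GRP7 at 0.41.

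Sugar starvation genes had medians of 0.23 on replicate 1 and 1.32 on replicate 2, with 0 of 21 passing, or 5 rising and 1 falling when adjusted over the list alone (adjusted p = 1.04e-04, and adjusted p = 0.775 with an estimated correlation). DIN2 had 3.04 and 5.39, and DIN11 went the other way, with a mean of -1.58. Touch and rapid stress genes had medians of 1.57 on replicate 1 and 0.15 on replicate 2, and TCH4 rose 4.02-fold, the 1 of 19 to pass by either adjustment (adjusted p = 1.35e-04, and adjusted p = 0.754 with an estimated correlation). ERF6 had 2.19 and 0.91. Among expansin and xyloglucan hydrolase genes, XTH18 rose 3.67-fold and EXPB1, well above background after auxin on 1 array, fell by 1.87 on the log2 scale, or 7 rose and 2 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.0730). The lists for hypoxia (adjusted p = 0.855), phosphate starvation (0.937), ribosome biogenesis (0.0994), cyclin-dependent kinase inhibitors (0.769) and light harvesting (0.867) did not pass, and 0 members passed by either adjustment. Their most extreme members were ADH1 (1.53) and LDH (-0.88), SPX1 (0.82) and RNS1 (0.73), NUC2 (1.15) and CBF5 (-0.68), KRP4 (0.67) and KRP1 (-0.26), and LHCB3 (-0.43) and LHCB1.5 (0.34). The median lay below 0 and the mean and test above it for hypoxia, phosphate starvation and cytokinin metabolism, and the reverse held for light harvesting. Reference genes had a median of 0.07 with 0 of 12 passing (adjusted p = 0.855), and UBQ10 had 0.71 and EF1A -0.69.

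**Figure D2:**
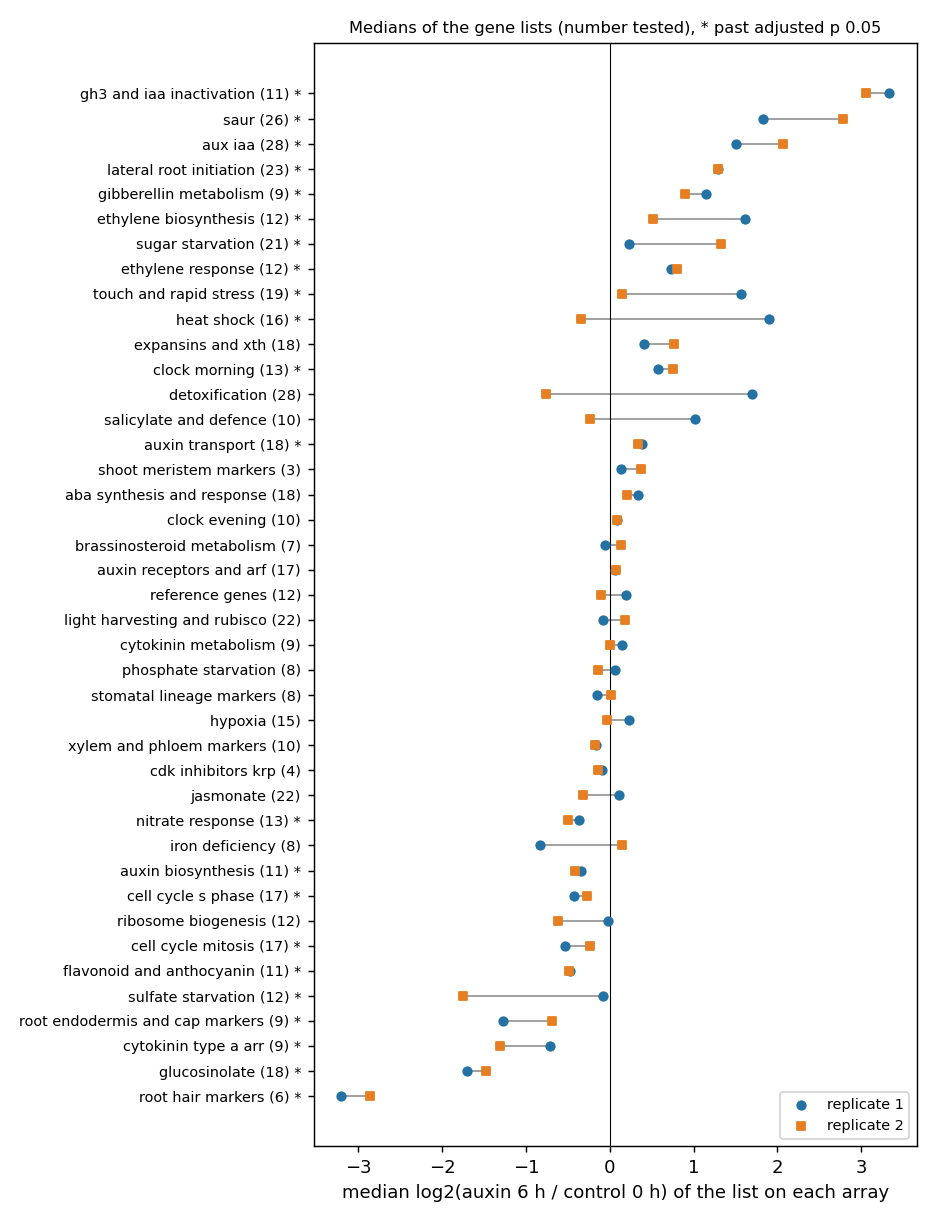
The horizontal axis gives the median log2 ratio of each gene list on replicate 1 (circles) and replicate 2 (squares), with the number of genes tested beside each name and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Root-hair markers lie lowest, at -3.21 and -2.86, and the medians for detoxification, at 1.69 and -0.77, lie on opposite sides of 0.

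The 2 arrays agreed in sign for 26 of 28 Aux/IAA genes. They differed in sign for 21 of 28 detoxification genes, 10 of 16 heat-shock genes and 7 of 10 salicylate and defence genes. The arrays also differed in sign for 7 of 13 nitrate response genes and 11 of 22 jasmonate genes. Across genes, which are not independent replicates, their log2 ratios had a Pearson r of 0.51 and a Spearman rho of 0.40, and 63.2% of genes had the same sign. Opposite changes of at least 1 on the log2 scale were found for 144 genes, of which 138 were higher on replicate 1. UGT74E2 had 2.81 on replicate 1 and -2.90 on replicate 2, and GSTU25 had 4.71 and -2.69. The 21 detoxification genes were all above 0 on replicate 1 and below 0 on replicate 2. GSTU12 and GSTU3 (at least 3.65-fold) rose, or 3 rose and 1 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.0730). Heat-shock genes had medians of 1.91 on replicate 1 and -0.34 on replicate 2, with 0 of 16 passing, or 4 rising when adjusted over the list alone (adjusted p = 0.00193, and adjusted p = 0.775 with an estimated correlation), a call also lost with median centring. HSP90.1 had 3.04 and -1.78. HSP21 and HSP22, not well above background in the control, were at least 3.01-fold and 2.69-fold higher without passing on their own (adjusted p = 0.107 and 0.139). Salicylate and defence genes had medians of 1.02 and -0.23, with 0 of 10 passing by either adjustment (adjusted p = 0.0934), and GRX480 had 3.66 and -0.58. CYP71A13, not well above background in the control, was at least 1.69-fold higher by the mean of the arrays, without passing on its own (adjusted p = 0.110).

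For detoxification and heat-shock genes the difference lay mostly in the control channel. For the 28 detoxification genes, the normalized Cy3 signal was higher in replicate 2 than in replicate 1 for all 28, by a median of 2.23 on the log2 scale. The Cy5 signal was higher in replicate 1 for 19 of them, and its median difference over all 28 was 0.27. Heat-shock genes had a median of -1.46 for replicate 1 minus replicate 2 in Cy3, and 0.57 in Cy5. Touch and rapid stress genes (-1.07 and 0.05) and salicylate and defence genes (-1.01 and 0.19) had the same pattern, so that the size of the rise of the touch list differs with the control RNA. SAUR genes (1.02 and 0.31), expansin and xyloglucan hydrolase genes (1.04 and 0.63) and Aux/IAA genes (0.55 and 0.03) were brighter in the control of replicate 1. The sizes of the SAUR and Aux/IAA rises thus also differ with the control RNA. Other lists parted more in the treated channel: the same medians were -0.19 in Cy3 and 1.21 in Cy5 for sulfate starvation, -0.57 and -1.46 for sugar starvation, and -0.12 and -1.24 for endodermis and cap genes. Over all genes, 2207 differed by at least 1 on the log2 scale between the Cy3 channels and 1053 between the Cy5 channels.

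**Figure D3:**
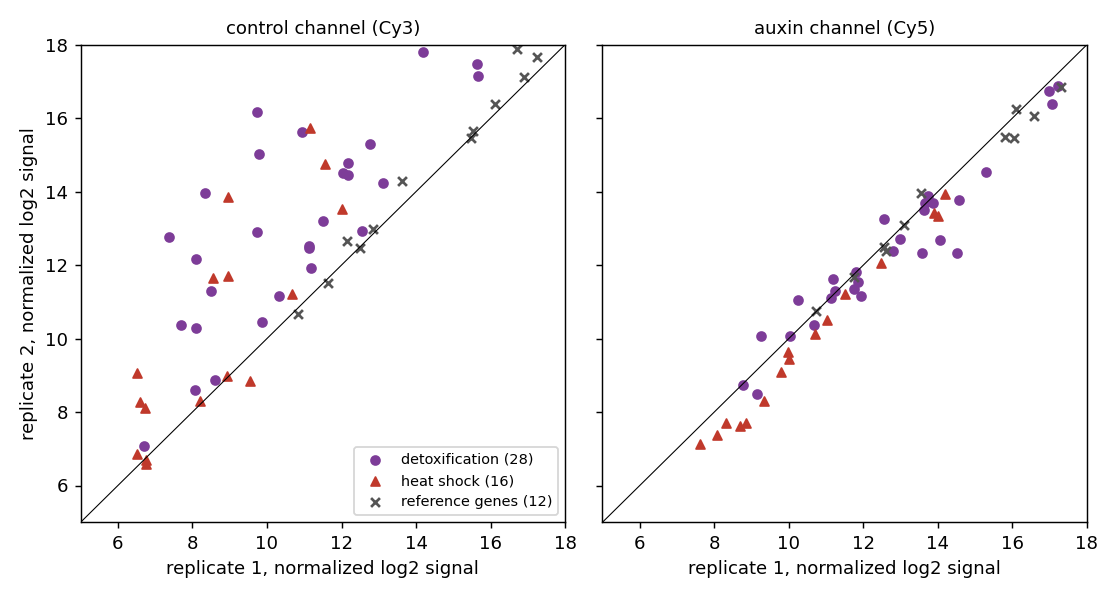
Each panel sets the normalized log2 signal of replicate 2 (vertical) against replicate 1 (horizontal), for the control channel on the left and the auxin channel on the right, with the line of equality. In the control channel all 28 detoxification genes (circles) lie above the line, while triangles mark heat-shock genes and crosses mark reference genes.

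**Figure D4:**
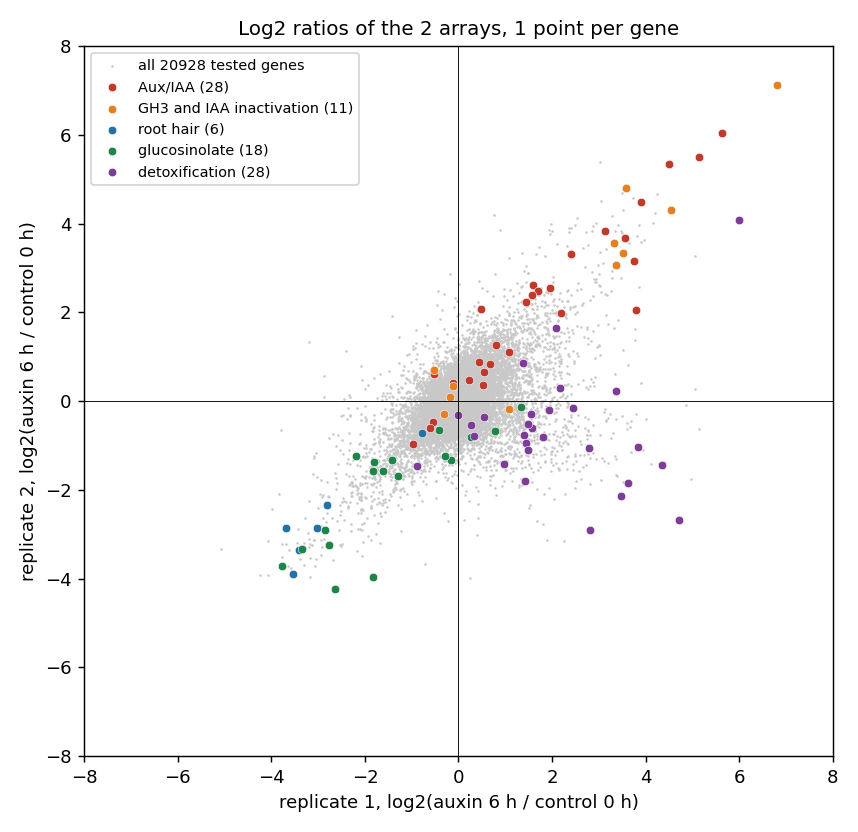
Each point is a gene, with its log2 ratio of auxin over control on replicate 1 (horizontal) and replicate 2 (vertical), and 5 gene lists in colour. Aux/IAA genes extend to the upper right and root-hair genes to the lower left, while many detoxification genes lie at the lower right.

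Because Cy5 always carried the treated RNA and no seedlings were kept for 6 h without auxin, dye, time of day, the stay in water and dimethyl sulfoxide changed together with auxin. The "at least" folds compare 2 channels and are open to dye bias for the same reason.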

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

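The tests of a dye exchange, of a lower root share and of time of day were chosen after the result was seen. The tests of the channels, of neighbouring spots and of probe GC content were written down after the patterns were seen and before the values they measure. After the channel values were seen, the name of the first pattern was narrowed from detoxification and heat-shock genes to detoxification genes, and a lower root share was reworded as the whole of the fall, with the tests unchanged.

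Probes left out of the gene tests, because they name several loci or none, carried signal too. Of 2862 such probes above background, 9 passed an adjusted p of 0.05 in a limma fit of all probes, 2 higher and 7 lower, and 49 changed by at least 1 on the log2 scale the same way on both arrays. The lowest were a probe shared by the peroxidase genes AT1G05250 and AT1G05240 (-4.04) and one with no locus, described as peroxidase 1/2 (-3.43). Both probes are named here after their values were seen, and whether they measure the same transcripts was not tested. Of 153 negative control spots, 2 were well above background on either array.

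Detoxification genes had opposite changes on the 2 arrays, with medians of 1.69 and -0.77. The tables argue against a difference of the treated RNA as the main source, since the Cy5 channel held 11.8% of the difference between the arrays, by medians. An exchange of dyes or tubes would have turned the Aux/IAA genes, whose lower array median was 1.51, and a local defect of an array would have reached the neighbouring spots, whose median difference was 0.00756. The control RNA differed between the replicates in the way this explanation needs: the Cy3 channel held 97.5% of the difference, by medians, and all 28 genes were brighter in replicate 2. The Cy3 and Cy5 shares split the same difference, so they are not separate evidence. Stress or handling of the replicate 2 control seedlings is a candidate explanation, and no biological explanation was tested, since nothing in the labels separates the 2 control samples.

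Root-hair genes fell, with a median of -3.10. A lower root share in the treated RNA, as the whole of the fall, would have lowered endodermis and cap genes as far. That holds only if the treatment itself left those genes unchanged. The endodermis and cap median lay 2.14 above the root-hair median (exact permutation test over 6 and 9 genes, two-sided p = 0.00799). Genes are not independent, so this p-value describes these genes and not the seedlings. Root-hair markers also had the lowest median of the 41 lists when this comparison was chosen, which favours a gap. Whether the treatment itself changed endodermis and cap genes was not tested. A share loss of the size of the endodermis and cap median, -0.97, or a larger one therefore stays open. A trend of the dye ratio with probe GC content left the median at -3.10 after its removal, a correction that moved 60 genes by at least 0.1. The largest move of any gene was 0.28, so a correction of this size could not have undone the fall. Auxin, the stay in water and the other dye effects changed together, so that a biological response to auxin may account for the fall but was not separated from them.

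Morning clock genes were higher as a list with camera at a preset correlation (adjusted p = 3.71e-05), a call lost with an estimated correlation (adjusted p = 0.722) and with fry (adjusted p = 0.199). Of 13 members 1 passed over all genes. The morning median lay 0.46 above the evening median, a difference that was not tested, both lists being on the upper side of 0. The labels give 6 h between the samples but no clock time, so time of day and auxin cannot be told apart for these genes.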

How the results depend on the processing

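The GC correction and its counts were chosen after seeing the data, and all other settings were planned. The 321 changed genes kept their direction in every setting that tested them, and 249 were tested where both channels had to be well above background. All had the same sign on both arrays to begin with, and the settings reuse these arrays, so this was nearly fixed in advance. Still called were 88 with no filter, 149 with no background correction, 162 with scaling between arrays and 320 with a trend and robust prior. The counts moved. Genes that rose and fell were 69 and 80 with no background correction, 255 and 308 with the authors' log ratios, 247 and 306 with the value table, 232 and 299 with normexp offset 0, and 74 and 88 with scaling between arrays. They were 42 and 46 with no filter, where 28476 genes were tested, and 262 and 318 with a trend and robust prior. At an adjusted p under 0.01 they were 0 and 0 (limma), with 3669 genes at an unadjusted p under 0.05. With median centring 277 rose and 203 fell, so that 57.7% of changed genes rose in place of 47.4%. That setting put the median of all genes at 0.31. The cause of these moves was not tested. Settings not named kept both counts within 1.5 times, and leaving out saturated spots removed none.

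Genes with a log2 ratio of at least 1 on both arrays numbered 465 up and 443 down, or 811 and 745 with the authors' log ratios, 803 and 742 with the value table and 806 up with median centring. On a single array, with no test, 933 to 1388 were up and 777 to 960 down. A Pearson r between arrays moved by under 0.1 in every setting.

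Of the 41 lists, 12 were higher and 10 lower with the preset correlation, and 0 and 0 with the estimated correlation and with fry (smallest adjusted p 0.722 and 0.0757, with 7 lists at an unadjusted fry p under 0.05). They were 9 and 10 with median centring, 13 and 9 with the authors' log ratios and the value table, 13 and 11 with no filter, 12 and 11 with both channels required, and 11 and 8 at an adjusted p under 0.01. Ethylene synthesis genes lost their call with median centring, with both channels required and at 0.01, flavonoid genes with the authors' log ratios, the value table and at 0.01, auxin biosynthesis genes at 0.01, and gibberellin and heat-shock genes with median centring. Expansin genes gained a call with the authors' log ratios, the value table, no filter and both channels required, and iron deficiency genes with median centring, no filter and both channels required. The nitrate median changed sign, to 0.22, with median centring (adjusted p = 0.113), where it lay below the median of all genes, 0.31. The heat-shock median was -0.34 without replicate 1 and 1.91 without replicate 2. Sizes moved in other lists too. Over the settings, single arrays included, the root-hair median lay between -4.23 and -2.86 and the Aux/IAA median between 1.18 and 2.11. Leaving out an array leaves no residual degrees of freedom, so gene and list tests could not be repeated. Signal over background limits the genes whose fold is a bound, 18 of those that rose and 14 of those that fell.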

Other observations

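These tests were chosen after the result was seen. Words in the probe descriptions that at least 20 tested genes carry, 382 in all, were counted among changed genes by a one-sided Fisher's exact test, with Benjamini-Hochberg adjustment. Genes are not independent, so the p-values describe the lists. Peroxidase genes were over-represented among those that fell, with 10 of 81 against 0.654 by chance (adjusted p = 1.98e-07), among them RHS19 at -3.45 and AT4G26010 at -3.36. Allergen-related genes gave 9 of 29 (adjusted p = 3.92e-10), and 6 of these are in the pollen allergen and extensin family, such as RHS13 at -3.33 and MOP10 at -3.20. Jacalin lectin genes gave 5 of 31 (adjusted p = 3.54e-04), pectinesterase genes 4 of 39 (adjusted p = 0.0115) and xyloglucan enzyme genes 4 of 28 (adjusted p = 0.00394), with XTH26 at -3.60. Expansin genes gave 4 of 25 (adjusted p = 0.00290), of which EXPA7 and EXPA18 are also root-hair markers.

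Among genes that rose, homeobox genes gave 5 of 50 against 0.363 by chance (adjusted p = 0.00235): WOX11, well above background in the control on 1 of the 2 arrays, rose 5.37-fold, HB53 4.88-fold, HB52 4.11-fold, HB18 3.38-fold and HB17 3.02-fold. WOX11 is known for its part in root formation from cuttings and leaves. Genes with inhibitor in their description were over-represented on both sides, with 6 of 142 among those that rose (adjusted p = 0.0330) and 6 among those that fell (adjusted p = 0.0322). Of those that rose, the endopeptidase inhibitor gene AT5G43570 rose to a mean log2 ratio of 3.59 and PDF2.1 rose 8.54-fold.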
